A study of Mus musculus with 4 samples.

How the data were processed

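RNA was counted in cells sorted for high CD45 from 4 mouse libraries, 1 each of aged brain, young brain, aged spleen and young spleen. Groups were taken from the labels, and ages in numbers are not given in the sources used here. Per the labels' protocols, cells were captured with the 10x Chromium 3' kit, version 2, and sequenced to at least 50000 reads per cell. The labels give a tamoxifen treatment and a search for tdTomato-positive NK cells for all 4 libraries, and whether it applied to these mice was not settled. They also call the cells of all 4 libraries neuroblasts, a label not used to name cells here.

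The deposited count matrices hold whole-number UMI counts per gene and barcode, not normalized and not filtered for cells. Per the file headers they have 31053 mouse genes and 6794880 barcodes and were written by software version 3.1.0. The submitters' processing notes name Cell Ranger 1.3.1 and GRCh38, a human build, which goes against those headers and the mouse gene identifiers, so the software and annotation behind the counts stay uncertain. Aligner settings and the counting of reads that match several genes are not given in the sources used here. Genes with near-identical copies are therefore uncertain. The authors' deposited tables give, per cluster of 1 library, a log ratio of mean expression against other cells, of which only values above 0.25 are listed. The log base is not stated, and slopes of the authors' values on natural log ratios recomputed from the counts were 0.925, 1.06, 0.986 and 0.873 in 1 cluster of each table, where a natural log gives 1 and log2 gives 1.44, so natural log was taken. The authors' deposited adjusted p-values, all below 0.05 as listed, were not used for a comparison of groups, and their test is not given in the sources used here. The map of cells to the authors' clusters was not used here.

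Barcodes counted as cells had at least 500 UMIs and 250 genes, at most 10% mitochondrial UMIs, and either lay above 10% of the 99th percentile of the top 3000 barcodes or differed from the ambient profile. The ambient profile came from barcodes of at most 100 UMIs, and the difference was tested with 10000 simulations at a false discovery rate of 0.01. Called barcodes numbered 10540 in the aged brain, 9703 in the young brain, 6181 in the aged spleen and 7153 in the young spleen, and the gene and mitochondrial filters left 9811, 8650, 5446 and 6582. Scrublet, run through scanpy, marked 156 and 238 doublets in the aged and young spleen, which were removed. In the brain libraries its automatic threshold marked 0.0204% and 0.0462%, under the floor of 0.5%, so the cells with the highest scores were removed at 0.8% per 1000 cells, 770 in the aged and 599 in the young brain.

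Cells were scaled to 10000 UMIs, and 2000 variable genes, 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1.0, with all libraries together and no integration. Clusters were named by 26 marker lists fixed before the data were examined, with a minimum score of 1.0. That minimum and the rules on low RNA, on mixture with microglia and on cycling genes were set after the data were seen, and together they left clusters 2, 3, 14 and 25 unnamed. Their cells in the aged brain, young brain, aged spleen and young spleen were 1913, 455, 0 and 0 for cluster 2, 51, 158, 0 and 0 for cluster 3, 47, 44, 64 and 42 for cluster 14, and 0, 334, 220 and 37 for cluster 25.

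UMIs were summed over the cells of a class in each library and given per 1e6 UMIs of the class (CPM). Shares have exact Clopper-Pearson intervals, CPM exact Poisson intervals and ratios exact conditional binomial intervals, all at 95%, for counting error only. A gene with 0 UMIs in 1 library was set at a floor of 3 counts over the class. With 1 library per group no test was made. Named classes with at least 50 cells in both libraries were compared, and NK-like cells in every case. T-like and erythroid-like cells of the brain and NK-like cells of young brain against young spleen were left out after the data were seen, because 15, 2 and 4 cells of the young brain lay outside shared barcodes.

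The rule for named genes was fixed before the data were examined. Among genes with at least 50 UMIs over both libraries, genes were ranked by the bound of the ratio interval nearest to 1, and the first 5 each way were named, or 10 for NK-like cells in brain. Immunoglobulin, T cell receptor variable, haemoglobin, ribosomal protein, mitochondrial and sex genes, unnamed gene models, and genes under 10% of their level in another class of at least 50 cells (RNA of other cells) were set aside. Added were 12 study genes, up to 4 members of each list and the leading genes of clusters. From the authors' tables the largest folds are given for clusters chosen after their values were seen, because they list Ncr1 or Gzma among NK genes, and the smallest folds are left out.

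The 24 gene lists, fixed before the data were examined, hold 6 to 98 genes. A list median is over members with at least 20 UMIs and needs 3 such members. Its percentile is among 10000 random lists of the same size, matched on mean expression in 20 bins, and lists outside the central 95% are reported apart, as a description of these libraries. Positions of 12 genes come from the reference annotation of GRCm38, which is not stated as the build of the counts.

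Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numba 0.67.0 and matplotlib 3.10.9. The steps were tested on simulated data. In the ambient test over 31053 genes, simulated on the aged brain at 600 UMIs per barcode, 0.5% of 400 ambient barcodes and 87.0% of 200 simulated cells were called. For NK-like cells of the aged over the young spleen, simulated over 9057 genes, 2-fold higher genes had a median ratio of 2.01 with the interval holding the truth for 95%, and 4-fold lower genes 0.247 and 98%. Intervals of unchanged genes excluded 1 for 4.18%. A raised list reached percentile 100 and a random list 3.89.

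Alternatives fixed before the data were examined were other cell calling rules, mitochondrial limits of 5% and 20%, doublets kept, resolutions of 0.5 and 2.0, lymphocytes as denominator, scalings by median of ratios or without ribosomal protein and mitochondrial genes, means over cells, subtraction of the ambient profile at 5%, cells thinned to 1000 UMIs, other UMI minimums of 20, 100 and 200, and stricter thresholds for the authors' tables. Added after the data were seen were the analyses without barcodes that hold more UMIs in another library, without genes that differ over 2-fold between 2 libraries at shared barcodes, and with 5 other seeds of the principal components and clustering. The seeds were added because 2 runs of the same code, made before each cell set had a process of its own, divided NK-like and T-like cells differently at a mitochondrial limit of 20% and slightly so at 500 UMIs without ambient test; every value given is from the later runs, which gave identical cells and clusters. The main seed was fixed before this and kept. The results of 3 genes that the rules would name are not reported here. A division of brain ratios by the ratios at shared barcodes was tried and dropped because it widened the spread. A first test of light-chain variable genes could not be used and was replaced by the constant region.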

Results

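RNA of single cells was measured in 4 mouse libraries, 1 each from aged brain, young brain, aged spleen and young spleen. The cells had been sorted for high CD45, a surface protein of leukocytes, and the study concerned natural killer (NK) cells and other immune cells in the aged brain. Each library counts unique molecular identifiers (UMIs), short random tags that mark single RNA molecules, per gene and cell barcode. The matrices held 57011537 UMIs in the aged brain, 26384220 in the young brain, 40628623 in the aged spleen and 39866955 in the young spleen. After filtering, 9041, 8051, 5290 and 6344 cells were left, in the same order, with medians of 2198, 1204, 4638 and 4125 UMIs per cell. With 1 library per group there was no replicate and no test, so a difference between ages or tissues is a difference between these libraries. All intervals are 95% intervals and cover counting error only.

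Clustering gave 26 clusters. In the brain libraries the largest class was microglia-like, the resident phagocytes of brain tissue. Its leading genes included Cx3cr1, Tmem119 and P2ry12 in cluster 0. In cluster 9 they included Fcrls and Sparc, behind Hist1h2ac, Gng10 and Hist1h1d. Border macrophage-like cells, which sit in the meninges and around vessels, were led by Ms4a7 at 75.4-fold and Mrc1 at 73.3-fold the level of all other cells. NK-like cells were led by Gzma at 46.8-fold, Klra4 at 27.8-fold and Ncr1 at 25.2-fold. T-like clusters were led by Ly6c2 and Trdc (cluster 5, with Cd3d behind them), by Cd3e (cluster 7, with 1076 cells of the young brain), by Cxcr6 and Cd226 (cluster 17), by Ctla4, Izumo1r and Foxp3 (cluster 18) or by Dapl1 and Cd8b1 (cluster 19). B-like and plasma-like cells, monocytes or macrophages, neutrophils, erythroid, endothelial, mural and choroid plexus cells were also named. Clusters 2 (low RNA), 3 (astrocyte and oligodendrocyte genes mixed with microglia), 14 (cycling) and 25 (led by Tbc1d4 at 110-fold and Il1r2 at 60.9-fold) stayed unnamed.

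The young brain library held most of its lymphocyte-like cells at barcodes of the aged spleen. Of its 8051 cells, 4701 (58.4%) had barcodes with more UMIs in another library. The young brain and aged spleen shared 4388 cell barcodes where 6.27 were expected by chance, and at all 4388 the aged spleen held more UMIs. All 1748 B-like and all 74 plasma-like cells of the young brain lay at such barcodes, as did 1688 of 1703 T-like and 665 of 669 NK-like cells. Only 8 of 2464 microglia-like and 2 of 209 border macrophage-like cells did. At the shared barcodes 4104 of 4206 named cells (97.6%) had the same class in both libraries, and the log10 UMIs per barcode correlated across barcodes with a Pearson's r of 0.937 (barcodes are not independent replicates). Many brain comparisons are therefore also given without shared barcodes, an alternative added after the data were seen; without them the young brain held 3350 cells with a median of 2299.5 UMIs.

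**Figure D1:**
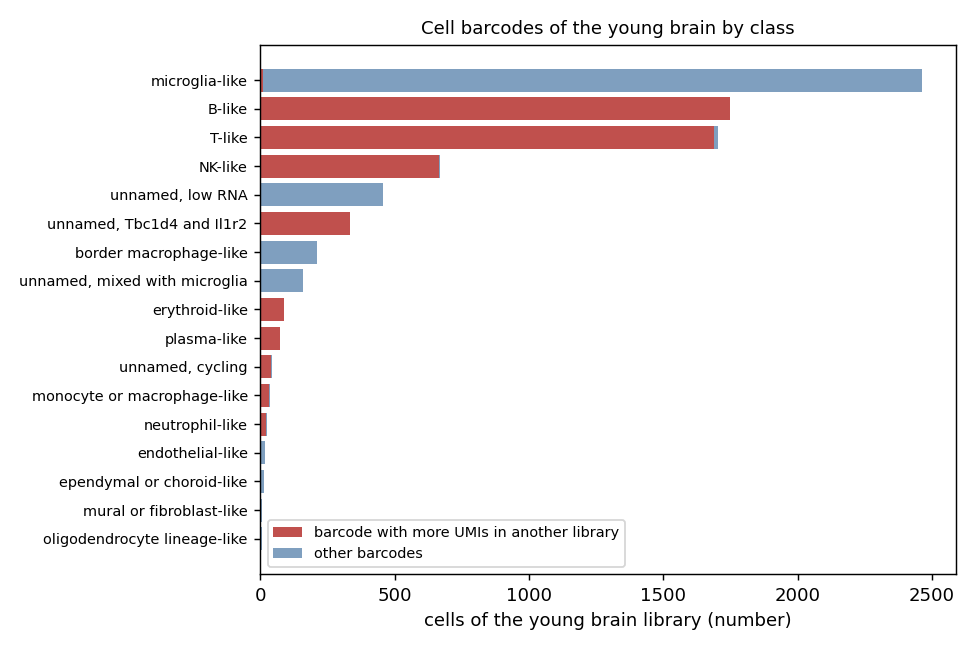
Cells of the young brain library per class, split by whether the barcode had more UMIs in another library. Nearly all NK-like, T-like and B-like cells (665 of 669, 1688 of 1703 and 1748 of 1748) lay at such barcodes, against 8 of 2464 microglia-like cells.

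The first comparison asked which cells made up the aged and young brain libraries after the sort for high CD45. Microglia-like cells made up 55.8% of the aged brain library (5043 of 9041, interval 54.7 to 56.8) and 30.6% of the young brain library (2464 of 8051), a ratio of 1.82 (1.74 to 1.91). Without shared barcodes the order turned, to 0.763 (0.727 to 0.801), against 73.3% of the young brain. The class lay in different clusters at the 2 ages: cluster 0 held 4804 aged and 114 young cells, and cluster 9 held 102 aged and 2312 young cells. Border macrophage-like cells took 9.43% of the aged and 2.60% of the young library, a ratio of 3.63 (3.12 to 4.25), which was 1.53 (1.32 to 1.79) without shared barcodes. NK-like cells were rare in the aged brain, with 19 of 9041 cells (0.210%, 0.127 to 0.328), and T-like cells numbered 89 (0.984%, 0.791 to 1.21). Against all young brain barcodes these shares gave ratios of 0.0253 (0.0151 to 0.0398) for NK-like and 0.0465 (0.0372 to 0.0576) for T-like cells. Without shared barcodes the young brain kept 4 NK-like and 15 T-like cells, and the ratios were 1.77 (0.588 to 7.16) and 2.19 (1.26 to 4.07). Of the 89 T-like cells of the aged brain, 83 lay in cluster 5, and many of these had no UMI of Cd3d, Cd3e or Cd3g. The counts, shares and ratios of both classes therefore depend on naming that cluster T-like, as described further below. The division of NK-like from T-like cells also varied with the settings. With 5 other clustering seeds, added after the data were seen, the young brain held 707 to 1094 NK-like cells against 669 here, and the aged brain 19 each time. With a mitochondrial limit of 20% the aged brain held 64 NK-like and 44 T-like cells.

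Cells other than leukocytes also differed between the brain libraries, which passed a sort for high CD45. Endothelial-like cells numbered 419 in the aged and 18 in the young brain, a ratio of 20.7 that was 8.66 without shared barcodes. Mural or fibroblast-like cells numbered 166 and 4, a ratio of 37.0 that was 15.5 without shared barcodes, and ependymal or choroid-like cells 210 and 15, at 12.5 and 5.19. Neutrophil-like cells, with 78 and 26 cells, gave a ratio of 2.67 (1.69 to 4.34), and 4.78 without shared barcodes. Cluster 2, whose cells held little RNA, took 21.2% of the aged and 5.65% of the young library, or 13.6% of the young library without shared barcodes, where the ratio was 1.56 against 3.74. Shares of such cells, and of microglia-like cells, can be set by the gate of the sort and by the UMI minimum.

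In spleen the question was whether the classes differed with age outside the brain. NK-like cells took 15.4% of the aged (817 of 5290, 14.5 to 16.4) and 29.2% of the young spleen library (1855 of 6344, 28.1 to 30.4), a ratio of 0.528 (0.486 to 0.574). As a share of lymphocyte-like cells they were 17.5% of 4669 and 31.2% of 5946. The genes that define this class were themselves lower in the aged spleen, as given for Gzma and Ncr1 with the NK-like genes. T-like cells gave a ratio of 1.23 (1.15 to 1.32), and B-like cells, at 38.1% and 38.0%, a ratio with an interval of 0.945 to 1.06. Plasma-like cells, which secrete antibody, numbered 128 in the aged and 13 in the young spleen, a ratio of 11.8 (6.66 to 22.8). Erythroid-like cells were also more frequent in the aged spleen, at 3.27 (2.33 to 4.66), while monocyte or macrophage-like and neutrophil-like cells gave ratios of 0.909 and 0.917 whose intervals included 1. With a mitochondrial limit of 5% per cell, which left 2235 aged and 3981 young cells, the NK-like ratio was 0.703. The T-like ratio was then 1.09 (0.988 to 1.20), with an interval that included 1. Before the mitochondrial filter, called cells had a median of 5.68% mitochondrial UMIs in the aged and 4.61% in the young spleen.

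Brain and spleen were compared within the aged mice, whose libraries shared few barcodes. NK-like cells were 0.210% of the aged brain and 15.4% of the aged spleen library, and T-like cells 0.984% and 32.3%, giving brain-to-spleen ratios of 0.0136 (0.00815 to 0.0214) and 0.0305 (0.0243 to 0.0377). Among the 116 lymphocyte-like cells of the aged brain, 16.4% were named NK-like and 76.7% T-like. These shares depend on the naming of cluster 5 as T-like, since 35 of its 83 cells in the aged brain had no UMI of Cd3d, Cd3e or Cd3g, and 16 of those 35 had a UMI of Ncr1. The NK-like share of lymphocytes was 17.5% in the aged spleen. The same comparison in young mice is not reported because 4 NK-like cells of the young brain lay outside shared barcodes.

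**Figure D2:**
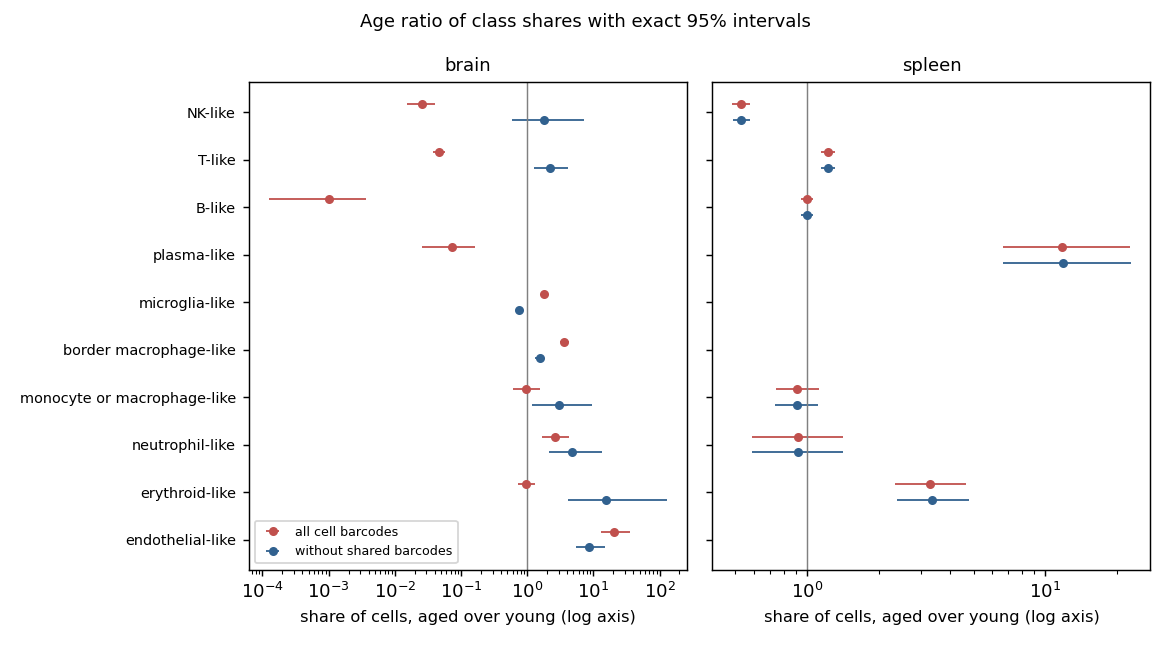
Ratio of the aged to the young share of cells for each class (log axis), in brain with all barcodes, in brain without shared barcodes and in spleen, with exact 95% intervals of counting error. The brain ratios of NK-like cells stood at 0.0253 with all barcodes and 1.77 without shared ones, and the spleen ratio at 0.528.

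Of the 12 study genes, 9 had lower levels in NK-like cells of the aged spleen, with intervals below 1. Gzma (granzyme A, a protease of cytotoxic granules; ENSMUSG00000023132, GRCm38 chromosome 13, 113093825 to 113100981) stood at 3823 counts per 1e6 UMIs (CPM) in the aged and 7273 in the young spleen, a ratio of 0.526 (0.516 to 0.535). Ncr1, the activating receptor NKp46 (ENSMUSG00000062524, chromosome 7, 4337724 to 4345164), gave 0.599 (0.564 to 0.635), and Klrg1, a receptor of mature NK cells (ENSMUSG00000030114, chromosome 6, 122270596 to 122282882), 0.466 (0.380 to 0.568). Prf1 (perforin), Klrk1 (NKG2D), Klrc1 (NKG2A), Itgam and Ifng gave 0.695, 0.664, 0.716, 0.606 and 0.865. Cd27 and Il27ra, at 0.959 and 1.10, had intervals that included 1, and Il2rb stood at 1.08 (1.04 to 1.12). Gzmb, at 0.909 (0.849 to 0.972), turned to 1.04 when each cell was thinned to 1000 UMIs. Sums rested on 817 and 1855 cells with 3938807 and 7925536 UMIs.

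**Figure D3:**
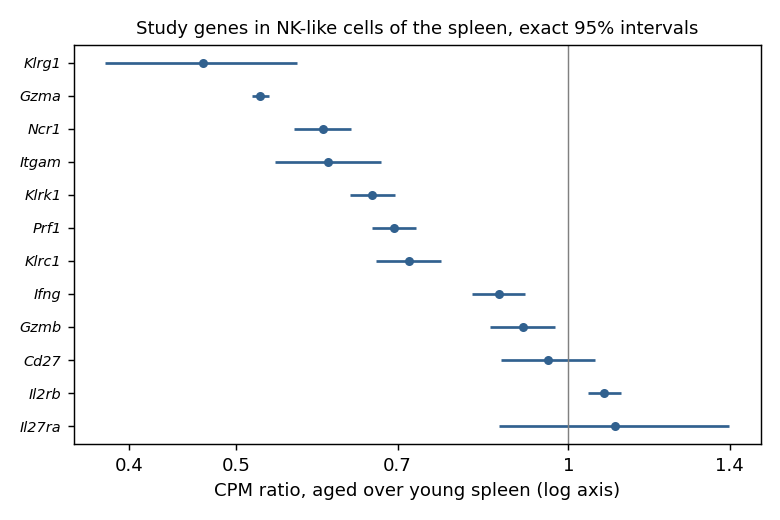
CPM ratio of aged to young spleen (log axis) for the 12 study genes in NK-like cells, with exact 95% intervals. Gzma stood at 0.526 (0.516 to 0.535).

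By the fixed rule of size, the genes with the highest ratios in NK-like cells of the spleen were Osgin1 (9.44, 5.13 to 18.7), the tetraspanin Cd63 (7.90), the orphan nuclear receptor Nr4a3 (4.84, 4.36 to 5.37), Maff (4.67) and Litaf (4.60). The lowest were Zfp606 (0.159), the fractalkine receptor Cx3cr1 (0.243, 0.164 to 0.350), Lsm10 (0.297), galectin-1 (Lgals1, 0.324) and the chemokine receptor Ccr2 (0.379). The median log2 ratio over all genes was -0.12. Activating receptors and adaptors had a median log2 ratio of -0.43 (17 measured, intervals above 1 for 2 and below 1 for 13), with Fcgr3 at 0.485 and Cd244 at 0.612. Inhibitory receptors stood at -0.50 (16 measured, 4 above and 11 below), with Klra5 at 0.418, Klra9 at 0.604 and Klre1 at 0.608. Interferon response genes stood at -0.59 (28 measured, 2 above and 16 below), with Mx1 at 0.262, Ifi47 at 0.465 and Ifi206 at 0.513. Nuclear genes of oxidative phosphorylation stood at -0.35, with 1 of 90 above and 74 below, while the 13 mitochondrial transcripts stood at 0.23. Immediate early genes, which respond within minutes to stimulation and to tissue dissociation, stood at 0.43 (22 measured, 15 above and 2 below), with Nfkbiz at 2.58, Nfkbia at 2.36 and Nr4a1 at 1.99. The list of T cell exhaustion and aging stood at 0.84 (11 measured) with Tox at 1.80 and Nr4a2 at 1.64, and the senescence list at 0.74 (7 measured) with the cell cycle inhibitor Cdkn1a at 2.55. These 8 lists lay outside the central 95% of random lists, as did class II antigen presentation at 0.31, whose members Cd74 and H2-Ab1 were marked as RNA of other cells and whose median was -0.04 with thinned cells.

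The other lists of NK-like cells in spleen lay inside the central 95% of random lists. Cytotoxic effectors had a median of -0.14, NK maturation -0.22, tissue residency 0.08, tissue egress -0.23, cytokines 0.18, chemokines 0.10 and cytokine receptors 0.08. Class I antigen presentation stood at 0.02, heat shock at 0.12, cell cycle at -0.18, cytosolic ribosome at -0.06, glycolysis at 0.05, damage-associated genes at -0.15 and sex genes at -0.03. Of the NKG2D ligands 1 member was measured, so no median was given.

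For NK-like cells in brain, the question of the study, the aged library gave 19 cells and 60054 UMIs and the young library 669 cells and 644552 UMIs, of which 4 cells and 9823 UMIs lay outside shared barcodes. The values below thus set aged brain cells mostly against barcodes that the young brain shared with the aged spleen. The class also lay in different clusters, with 15 of the 19 aged cells in cluster 6 and 619 of the 669 young cells in cluster 21. Higher in the aged brain were the cathepsin Ctss (11.9, 7.47 to 18.9), S100a6 (9.08), S100a4 (8.14), Hist1h1e (5.26), Tmem167 (4.91), Atp5j (4.60), Clec2d (4.07), Atp5l (3.78), Ccr2 (3.61) and AW112010 (3.37). Lower were Ccl3 (0.0188, 0.000474 to 0.105), Tnfaip3 (0.0284), Nfkbia (0.0534), Dusp1 (0.0551), Junb (0.129) and Lars2 (0.137). Nr4a2, Hes1, Nr4a1 and Ifng had 0 UMIs in the aged brain, and at a floor of 3 counts their ratios were at most 0.0469, 0.0491, 0.0836 and 0.153. Gzma gave 1.36 (1.20 to 1.53) and Ncr1 1.69 (1.09 to 2.55), but 0.265 and 0.442 without shared barcodes; Ctss, AW112010 and Junb also turned, to 0.981, 0.840 and 1.42. With median-of-ratios scaling Gzma stood at 0.774 and Ncr1 at 0.967. Gzmb (1.42), Prf1 (1.02), Klrk1 (1.19), Klrg1 (1.79), Cd27 (0.370), Itgam (1.12), Il2rb (0.827) and Il27ra (0.894) had intervals that included 1, and Klrc1 gave 0.342 (0.109 to 0.815).

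In the same comparison the lists of T cell exhaustion and aging (-2.85, 4 measured), immediate early genes (-2.41, 0 above and 17 below of 19), chemokines (-1.90, 4 measured) and heat shock (-1.05) lay below random lists. Cytosolic ribosome (1.05, 73 of 83 above), cell cycle (0.87), damage-associated genes (0.81) and oxidative phosphorylation (0.69, 27 of 74 above and 0 below) lay above them. The damage-associated list was made for microglia or macrophages, but its members Ccl4 and Ccl3 also lead NK-like cluster 6, at 20.5-fold and 16.7-fold. Both were lower in the aged brain here, so neither raised the median of that list. Its member Apoe, at 11.2, was marked as RNA of other cells in this comparison. Named members included Nr4a3 at 0.0521, Eomes at 0.370, Ccl4 at 0.231, Xcl1 at 0.310, Hspa5 at 0.370 and Stmn1 at 13.4. Without shared barcodes too few members of the exhaustion and chemokine lists were measured for a median, immediate early genes stood at -0.39 with 3 members, oxidative phosphorylation at -0.03 and damage-associated genes at -0.09. The cell cycle list turned to -0.05 with thinned cells. Heat shock turned to 0.33 with the order-of-magnitude cutoff alone, which left 4 NK-like cells in the aged brain. Oxidative phosphorylation turned to -0.12 with median-of-ratios scaling. The remaining lists with a median ranged from -1.07 (class II antigen presentation) to 0.63 (NK inhibitory receptors).

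Between aged brain and aged spleen, 19 and 817 NK-like cells were compared at barcodes of their own. Ctss was 19.4-fold (13.4 to 27.5) higher in the aged brain, the ectonucleotidase Entpd1 11.2-fold, Grn 10.2-fold, Stmn1 9.65-fold and S100a6 7.54-fold. Lower in the brain were Ccl3 (0.0122), Tnfaip3 (0.0199), Nfkbia (0.0601) and, with 0 UMIs in the brain, Nr4a2 (at most 0.0483), Nr4a1 (at most 0.0610) and Ifng (at most 0.109). Gzma gave 1.32 (1.17 to 1.48), Klrc1 0.289 (0.0938 to 0.677), Cd27 0.325 and Il2rb 0.718, while the intervals of Ncr1 (1.25), Gzmb (1.01), Prf1 (1.32), Klrk1 (0.931), Klrg1 (1.59), Itgam (1.10) and Il27ra (0.602) included 1. All 20 measured immediate early genes had intervals below 1, with a median of -2.76, and chemokines stood at -2.32, heat shock at -0.66, class II antigen presentation at -1.82 and sex genes at -0.94. The class II median turned to 1.92 with the order-of-magnitude cutoff alone and to 1.66 with a mitochondrial limit of 20%. Tissue residency genes stood at -0.38, with Itga1, the integrin CD49a, at 7.67 against Xcl1 at 0.200, Rgs2 at 0.198 and Bhlhe40 at 0.0550. Inhibitory receptors stood at 0.79 (Klra3 2.47, Klra7 1.95), cell cycle at 0.89 (Mcm7 7.41), damage-associated genes at 0.92, oxidative phosphorylation at 0.56 and cytosolic ribosome at 0.41. With a mitochondrial limit of 20%, inhibitory receptors turned to -0.0879 and cell cycle to -0.14. Interferon response genes had a median above 0 with Ifi47 at 6.42, but stood at -0.21 over members with at least 100 UMIs. Apoe, at 20.4, is among the 10 leading genes of border macrophage-like cluster 8, at 52.8-fold, and was marked as RNA of other cells. Ctss, which was not marked, is among the 10 leading genes of microglia-like cluster 0. Microglia-like cells made up 55.8% of the aged brain library but 0 of 5290 cells of the aged spleen. Whether their RNA also raised Entpd1, Grn or other genes named here was not tested. The other lists ranged from -0.48 (cytokines) to 0.52 (glycolysis).

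Microglia-like cells, which hardly shared barcodes, were compared in 5043 aged and 2464 young cells that lay mostly in clusters 0 and 9. Class I antigen presentation had a median log2 ratio of 0.56 (15 measured, 10 above and 0 below), with H2-Q6 at 3.20, B2m at 2.41 (2.34 to 2.48) and H2-K1 at 1.93; it was 0.55 without shared barcodes. B2m also differed 1.38-fold between the aged spleen and the young brain library at their shared barcodes. Immediate early genes stood at -0.64 (0 above and 17 below of 22), with Fosb at 0.343 and Fos at 0.402, and heat shock genes at -0.27 with Hspa1a at 0.192 (0.159 to 0.231). Damage-associated genes stood at -0.22 (19 measured, 6 above and 10 below), with Cd9 at 0.669 but Itgax at 2.24. Glycolysis stood at 0.38 (Eno1 2.58, which was 2.80 between libraries at shared barcodes), class II antigen presentation at 0.34 (Cd74 2.54, marked as RNA of other cells), mitochondrial transcripts at 0.54 (mt-Co1 3.69), cytosolic ribosome at 0.40 and oxidative phosphorylation at -0.05, which turned to 0.0026 with the total taken without ribosomal protein and mitochondrial genes. Without genes that differ over 2-fold between libraries at shared barcodes, mitochondrial transcripts stood at 0.43 over 10 members. Glycolysis then stood at 0.39 and cytosolic ribosome at 0.40. With all genes, the other lists ranged from -0.10 (tissue residency) to 0.58 (NK inhibitory receptors).

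By the rule of size, the genes with the highest ratios in microglia-like cells were Ildr2 (18.0, 11.6 to 29.7), Kcnj12 (12.9, 4.28 to 63.9), Zkscan2 (10.2), Psme2b (9.99) and Adrm1 (6.75). The lowest were Olfr482 (0.0766), Tpm3-rs7 (0.101), Wdr89 (0.126), Hmga1b (0.135) and Ftl1-ps1 (0.157). Several of these have near-identical copies, between which reads can be split, and their values are uncertain. At the barcodes shared by the young brain and the aged spleen, the library of the aged spleen differed from that of the young brain in the same direction for Psme2b (4.84), Adrm1 (3.87), Tpm3-rs7 (0.175), Wdr89 (0.127) and Ftl1-ps1 (0.121). Over the 7835 genes measured there, 178 (2.27%) differed more than 2-fold. These included 26 of the 75 genes over 2-fold lower in aged microglia-like cells (34.7%, with 0.926 genes expected) and 9 of the 65 over 2-fold higher (13.8%, with 0.652 expected), in the same direction. Without those genes class I antigen presentation stayed at 0.56 and immediate early genes stood at -0.68.

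Border macrophage-like cells of the aged brain (853 cells against 209) carried more class II antigen presentation RNA. This list had a median of 0.94 (11 measured, 10 above and 0 below), and 0.93 without shared barcodes. Its chaperone Cd74 was 3.57-fold (3.35 to 3.81) higher, H2-Eb1 1.91-fold and H2-Aa 1.87-fold. The median depended on the filters, at 0.23 with doublets kept and 0.52 with a minimum of 1000 UMIs. By the rule of size the genes with the highest ratios were Cd209a (18.0, 6.97 to 66.5), Cd209d (21.0, 3.68 to 837) and Slamf7 (15.2, 4.15 to 127), with Retnla and Mlph at 0 UMIs in the young brain and at least 9.15-fold and 4.78-fold higher in the aged. The lowest were Mobp, a myelin gene (0.124), Tpm3-rs7 (0.131), Wdr89 (0.150), Ftl1-ps1 (0.159) and Isg15 (0.218, 0.153 to 0.311). Mobp also leads unnamed cluster 3 at 33.2-fold. Tpm3-rs7, Wdr89 and Ftl1-ps1 differed in the same direction between libraries at shared barcodes, as given for microglia-like cells. Of 30 genes over 2-fold lower, 8 (26.7%, with 0.655 expected) differed so at over 2-fold. Of 28 over 2-fold higher, 3 (10.7%, with 0.548 expected) did. Interferon response genes stood at -0.50 (1 above and 14 below of 31), with Ifi206 at 0.383 and Bst2 at 0.512, and immediate early genes at -0.46 with Fosb at 0.397. NK inhibitory receptors stood at 1.38 (4 measured, Lag3 3.63 and Havcr2 2.45), T cell exhaustion and aging at 1.29 (5 measured), NK maturation at 0.56 (Cx3cr1 1.77), cytosolic ribosome at 0.67, glycolysis at 0.49 and oxidative phosphorylation at -0.18. Without shared barcodes these 8 medians were -0.52, -0.45, 1.36, 1.28, 0.54, 0.66, 0.47 and -0.18. Without the genes that differ between libraries at shared barcodes, NK maturation stood at 0.33 and glycolysis at 0.38, both inside the central 95% of random lists. The other lists ranged from -0.29 (sex genes) to 0.57 (cytokines).

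T-like cells of the spleen were compared in 1710 aged and 1669 young cells. The list of T cell exhaustion and aging had a median of 1.52 (14 measured, 12 above and 2 below), with granzyme K (Gzmk) at 24.6 (11.1 to 68.1), the inhibitory receptor Lag3 at 8.26 (6.03 to 11.6), Tox2 at 6.36 and Sostdc1 at 4.97. By the rule of size, osteopontin (Spp1) was 120-fold (40.7 to 584) higher, the growth factor Areg 28.0-fold, the cytokine Il10 24.9-fold and Rgs16 18.3-fold, and Esm1, with 0 UMIs in the young spleen, at least 23.3-fold. Lower were Il17rb (0.147), Rmdn2 (0.156), Asb2 (0.182), the chemokine receptor Cxcr6 (0.197, 0.180 to 0.215) and Cd226 (0.263). Cxcr6 and Cd226 lead cluster 17, which held 175 aged and 604 young cells, and Rgs16 leads cluster 18, which held 621 and 164. Ctla4 and Izumo1r, members of the exhaustion list, also lead cluster 18. Whether the greater number of its cells in the aged spleen set the median of that list was not tested. Activating receptors stood at -1.09 (1 above and 15 below of 17; Cd160 0.325), inhibitory receptors at -0.34 with Tigit at 7.06 against Klra1 at 0.424, and cytokine receptors at -0.35 (Il12rb2 0.457, Il21r 1.70). Interferon response genes stood at -0.56 (1 above and 21 below of 31; Ifi47 0.457, Ifi206 0.473) and oxidative phosphorylation at -0.38 (2 above and 78 below of 89). Immediate early genes stood at 0.40 (Junb 1.64), senescence at 0.51 (Cdkn1a 4.27), mitochondrial transcripts at 0.20, class II antigen presentation at 0.22 (Cd74 1.29, marked as RNA of other cells) and damage-associated genes at 0.18, which turned to -0.05 with thinned cells. The other lists ranged from -0.15 (cytotoxic effectors) to 0.20 (cytokines).

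B-like cells of the spleen (2014 aged and 2409 young cells) had lower interferon response genes in the aged library, with a median of -0.71 (0 above and 25 below of 29), Ifi27l2a at 0.398 (0.376 to 0.421), Ifit3 at 0.394 and Ifi47 at 0.463. Most aged cells lay in cluster 23 (1261 aged, 186 young), led by Egr3 and Irf4, and most young cells in cluster 24 (601 aged, 2149 young), led by Ly6d and Cd79b. Oxidative phosphorylation stood at -0.37 (2 above and 78 below of 89). The list of T cell exhaustion and aging stood at 0.82 with Nr4a2 at 2.47, senescence at 0.70 with Plaur at 2.56, which also leads cluster 23, immediate early genes at 0.14 with Nr4a1 at 2.33 but Fos at 0.591, and mitochondrial transcripts at 0.13. By the rule of size the genes with the highest ratios were Pnma1 (14.4, 5.86 to 45.8), Nav2 (6.75), Rab20 (6.50), Lncpint (4.56) and Hs3st1 (4.24), and among the lowest were Snx32 (0.247), Hist1h2an just above it, Usp50 (0.269) and Il4i1 (0.352). Cytotoxic effectors (-0.43), activating receptors (-1.07) and inhibitory receptors (-1.18) rested largely on RNA of other cells, with Gzma at 0.311, and with a mitochondrial limit of 5% they stood at 0.63, 0.76 and 1.25. The senescence median was -0.13 over members with at least 100 UMIs. The other lists ranged from -0.32 (tissue egress) to 0.28 (chemokines).

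Monocyte or macrophage-like cells of the spleen were few (166 aged and 219 young cells). By the rule of size the neutrophil-attracting chemokine Cxcl3 and arginase 1 (Arg1) had 0 UMIs in the young spleen and were at least 34.4-fold and 24.1-fold higher in the aged. Ccl7 was 131-fold (interval up to 5243) and Saa3 109-fold (19.0 to 4342) higher, each on 1 UMI in the young spleen, and S100a8, an abundant transcript of neutrophils, 27.3-fold (18.9 to 40.8). Lower were Klra2 (0.212), Jchain (0.236), Fcmr (0.242), Fcna (0.282) and lysozyme (Lyz2, 0.332, 0.315 to 0.349). Jchain, a plasma cell transcript, turned to 1.04 as a mean over cells. Interferon response genes had a median of -1.02 (1 above and 16 below of 23), with Usp18 at 0.107, Ifi206 at 0.115 and Ifi27l2a at 0.403. Chemokines stood at 0.44 (Ccl2 6.18), glycolysis at 0.42 (Gapdh 2.13), senescence at 0.73 (Il6, with 0 UMIs in the young spleen, at least 8.94-fold), heat shock at 0.31 and immediate early genes at 0.18. Activating receptors stood at -0.52, class I antigen presentation at -0.21, damage-associated genes at -0.23 (Apoe 0.504) and cytosolic ribosome at -0.07. As means over cells, heat shock, cytosolic ribosome and glycolysis turned sign. Of the 20 genes ranked highest and lowest, 6 were kept with means over cells and 2 with thinned cells. The other lists ranged from -0.15 (cytokine receptors) to 0.12 (tissue residency).

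**Figure D4:**
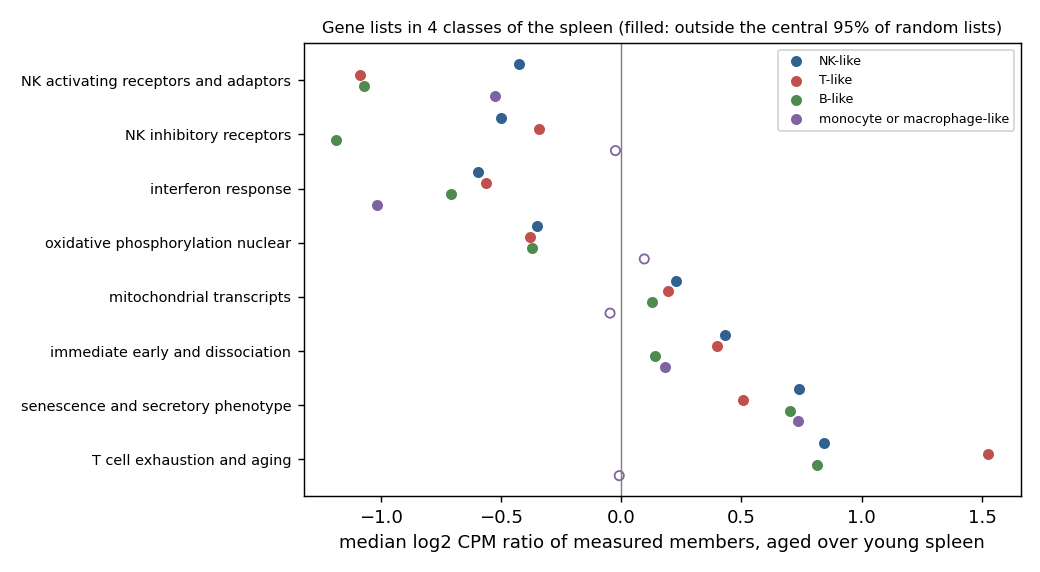
Median log2 ratio of aged to young spleen for the gene lists in NK-like, T-like, B-like and monocyte or macrophage-like cells, with filled points for medians outside the central 95% of random lists. The interferon response medians were -0.59, -0.56, -0.71 and -1.02.

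The authors' deposited tables list genes that mark each of their clusters within a library, and hold no comparison between ages or tissues. The authors' deposited table of the aged brain lists 3646 genes over 13 clusters, that of the young brain 4256 over 13, that of the aged spleen 4320 over 15 and that of the young spleen 3943 over 16, a gene being counted once per cluster. In the authors' deposited table of the aged brain, Ncr1 is listed in cluster 11, at 3.05-fold, with Ccl5 at 41.5-fold, AW112010 at 11.7-fold and Tmsb10, Nkg7 and Ms4a4b behind them. In the authors' deposited table of the aged spleen, cluster 2 lists Gzma at 20.2-fold, Ccl4, Ccl5, Ccl3 and Klra4, with Ncr1 at 4.07-fold. In the authors' deposited table of the young spleen, Ncr1 is listed in cluster 1 at 4.59-fold, where Gzma stands at 16.2-fold, in cluster 13 at 2.76-fold, led by Xcl1 at 5.65-fold, and in cluster 15 at 2.04-fold, with C1qa at 3.30-fold. In the authors' deposited table of the young brain, cluster 5 is led by Gzma at 28.5-fold, Ccl5 at 15.7-fold and Ccl4 at 10.8-fold. Of the NK-like cells named here in that library, 665 of 669 lay at barcodes with more UMIs in another library. Whether the authors' cluster holds those barcodes was not determined. Folds are powers of e of the deposited log values, a base inferred from the data.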

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

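Of the tests below, those of chance reuse, of lymphocytes with barcodes of their own, of the age of brain cells and of the age of mice were chosen only after the result was seen.

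With all barcodes, several aged to young differences had opposite directions in brain and spleen, and none of these differences was tested. The T-like share had an aged to young ratio of 0.0465 in brain and 1.23 in spleen, and the plasma-like share 0.0722 and 11.8. In NK-like cells the median log2 ratio of T cell exhaustion and aging genes was -2.85 in brain and 0.84 in spleen, that of immediate early genes -2.41 and 0.43, and that of oxidative phosphorylation genes 0.69 and -0.35. Without shared barcodes the T-like brain ratio was 2.19 (1.26 to 4.07), in the direction of the spleen, plasma-like cells numbered 4 in the aged and 0 in the young brain, and oxidative phosphorylation in NK-like brain cells stood at -0.03. For the exhaustion and aging list in NK-like brain cells, too few members were measured without shared barcodes for a median. The immediate early median stayed negative there, on few members. With all barcodes the exhaustion and aging list also rested on few members in brain, Nr4a2 and Nr4a3 among them. With all barcodes but median-of-ratios scaling, oxidative phosphorylation in NK-like brain cells stood at -0.12, also in the direction of the spleen. In brain the values with all barcodes rest on young brain barcodes that 99.5% of its lymphocyte-like cells share with other libraries.

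UMIs also appeared in one library at the cell barcodes of another, counted here over the barcodes of each library that do not hold more UMIs elsewhere. At cell barcodes of the aged spleen a UMI was found for 100% in the young brain, 99.9% in the aged brain and 99.4% in the young spleen. At those of the young spleen this was 94.5% in the aged spleen, with a median of 3 UMIs and against 14.6% of all barcodes, and 26.3% in the young brain, against 12.1%. At the 3350 such barcodes of the young brain it was 38.8% in the aged brain, against 15.8%. The aged spleen barcodes held a median of 891 UMIs in the young brain, 54 in the aged brain and 13 in the young spleen.

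The first pattern weighed is the sharing of cell barcodes by the young brain and the aged spleen. Chance reuse is argued against by a number 700.1 times that expected, and lymphocytes with barcodes of their own by a sharing 99.2 percentage points more frequent in lymphocyte-like than in microglia-like cells. Reads of one set of cells counted in both libraries may be the source. Of 78 B-like barcodes led by lambda light chains in the aged spleen, 73.1% (61.8 to 82.5) were led by lambda in the young brain, against at most 14.1% in 1000 permutations, but the bar of 80% set in advance was not reached and lies inside the interval. Of 1484 barcodes led by kappa light chains in the aged spleen, 2.02% (1.37 to 2.87) were led by lambda in the young brain. These values argue against unrelated cells in the 2 libraries at the B-like barcodes tested. Because the bar was not reached, reads of the same cells in both libraries remain a proposed source only. No explanation by age or tissue was tested.

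The second pattern is a set of 8 genes with copies that differed over 2-fold between aged and young microglia-like cells, such as Tpm3-rs7 and Ftl1-ps1. At shared barcodes the copies differed by a median of 5.07-fold in the same direction, aged spleen against young brain. This argues against the age of the brain cells only if those barcodes hold the same cells in both libraries. The light chains argue against unrelated cells there, but the bar set in advance was not reached. If the cells are not the same, the libraries compared there also differ in age, and the value decides nothing. Over the 8 pairs as a set, whether reads were split differently between gene and copy stays open. The median absolute log2 ratio was 2.54 for the copies and 0.40 for the sums of gene and copy. In 3 of the 8 pairs, however, the copy made up at most 1.13% of the sum, which then follows the gene whatever the cause. In the remaining pairs, with copies at 14.1% of the sum or more, every copy was lower and its gene higher in aged cells. Rpl10-ps3 stood at 0.117 with Rpl10 at 10.0, and Rps27rt at 0.117 with Rps27 at 3.15. Ratios of the sums in these pairs ran from 1.01 to 1.49. Such opposite movement goes with a split of reads in these pairs.

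The third pattern is the lower interferon response in 4 classes of the aged spleen, with Ifi47 at 0.465 in NK-like cells. Thinned cells kept at least 78.9% of the median in each class, but this cannot decide on depth. Levels were sums per 1e6 UMIs, whose expected ratio hardly changes when each cell is thinned. Thinning mainly gives cells equal weight and drops those under 1000 UMIs. Of the monocyte or macrophage-like cells it kept 83 of 166 aged and 116 of 219 young ones. After subtraction of the ambient profile at 5%, at least 99.5% was left. That fixed 5% was not estimated from the data and can hardly move the ratio of genes near their ambient level. RNA of other cells as a cause therefore stays open. Age and library cannot be told apart with 1 library per age and tissue, so an effect of age may be proposed only as a hypothesis.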

How the results depend on the processing

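The analyses without shared barcodes and with other clustering seeds were chosen after the data were seen, as was the choice of the main results and of the results compared below. Over the alternatives fixed in advance, 727 of 869 gene ratios, 700 of 909 list medians and 109 of 158 share ratios stayed within the interval, and 6, 27 and 4 turned direction. Over those added later it was 45 of 63, 48 of 54 and 102 of 115, with 5, 2 and 3 turned. Lists of named genes stayed within 1.5 times in 37 of 50. No paired analysis was possible because each group has 1 library and the results come from no test. The causes of the differences below were not tested.

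Without shared barcodes the aged to young brain shares were 1.77 for NK-like, 2.19 for T-like, 1.53 for border macrophage-like and 0.763 for microglia-like cells. In NK-like cells of the brain Ctss stood at 0.981, AW112010 at 0.840, Junb at 1.42, Ncr1 at 0.442, Gzma at 0.265, oxidative phosphorylation at -0.0271 and damage-associated genes at -0.0885. Those values rest on 4 young cells. With lymphocytes as denominator and all barcodes the brain shares were 1.03 for NK-like, 1.89 for T-like and 2.93 for plasma-like cells, and with lymphocytes as denominator but without shared barcodes 0.799 for NK-like and 0.986 (0.567 to 1.84) for T-like cells.

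With the order-of-magnitude cutoff alone, shares were 0.0496 for NK-like and 0.0276 for T-like cells in brain, 0.485 and 1.39 in spleen, and 0.915 for microglia-like cells. There, heat shock stood at 0.33 and Gzma at 0.0168 in NK-like cells of the brain, class II at 1.92 in NK-like cells of aged brain over aged spleen and 0.52 in border macrophage-like cells, and immediate early genes at -0.47 in microglia-like cells. It left 4 NK-like cells in the aged brain. With a minimum of 1000 UMIs the brain shares were 0.0287 for T-like, 2.65 for border macrophage-like and 1.45 for microglia-like cells, cell cycle in NK-like brain cells was -0.24 and class II in border macrophage-like cells 0.52. With 500 UMIs and no ambient test the border macrophage-like and microglia-like shares were 2.97 and 1.70, and class II in border macrophage-like cells was 0.78.

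With a mitochondrial limit of 5% the NK-like and T-like shares in spleen were 0.703 and 1.09, microglia-like 2.10, class II in border macrophage-like cells 0.55 and, in B-like cells, cytotoxic effectors 0.63, activating receptors 0.76, inhibitory receptors 1.25 and mitochondrial transcripts -0.0049. With 20% the brain shares were 0.0788 for NK-like and 0.0247 for T-like cells, and class II in border macrophage-like cells 0.82. In NK-like cells Gzma was then 0.594 and cell cycle -0.0429 in aged over young brain, and in aged brain over aged spleen class II was 1.66, inhibitory receptors -0.0879 and cell cycle -0.14. At that limit the aged brain held 64 NK-like and 44 T-like cells, against 19 and 89 in the main analysis. An earlier run of the same code divided these cells differently at this limit. With doublets kept the T-like brain share was 0.0725 and class II in border macrophage-like cells 0.23. Over 5 other clustering seeds the young brain held 707 to 1094 NK-like cells, all above the 669 of the main seed, while the aged brain held 19 with each. The largest change came with seed 2, where the NK-like share in brain was 0.0155 and the T-like share 0.0621, and none of the main shares turned with a seed. At resolutions of 0.5 and 2.0 the microglia-like share was 1.73 and 1.64.

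With median-of-ratios scaling NK-like brain cells had Ncr1 at 0.967, Gzma at 0.774 and oxidative phosphorylation at -0.12. With the total taken without ribosomal protein and mitochondrial genes oxidative phosphorylation in microglia-like cells was 0.0026. With cells thinned to 1000 UMIs, cell cycle in NK-like brain cells was -0.0524, and in spleen class II in NK-like cells -0.0441, Gzmb 1.04, damage-associated genes in T-like cells -0.0536, senescence in B-like cells -0.0037 and cytosolic ribosome in monocyte or macrophage-like cells 0.00025. Over members with at least 100 UMIs, interferon response in NK-like cells of aged brain over aged spleen was -0.21, exhaustion in T-like cells 1.45 and senescence in B-like cells -0.13. As means over cells, cytotoxic effectors in B-like cells were 0.0586 and, in monocyte or macrophage-like cells, heat shock -0.0037, cytosolic ribosome 0.10, glycolysis -0.0251 and Jchain 1.04. With the ambient profile subtracted, B-like cells had cytotoxic effectors at 0.29, activating receptors at 0.17 and senescence at -0.11.

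At a fold of at least 2, the authors' deposited tables list 1241 genes for the aged brain, 1684 for the young brain, 998 for the aged spleen and 712 for the young spleen. NK-like cells of the brain were few, at 4 cells and 9823 UMIs in the young library without shared barcodes and 19 cells and 60054 UMIs in the aged.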

Other observations

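The cells and genes described here were chosen after their values were seen, with no test. Cluster 5, named T-like, held 83 cells of the aged brain, many with little CD3 RNA, the signalling part of the T cell receptor. With cells thinned to 1000 UMIs, 40 of 82 cells (48.8%, 37.6 to 60.1) had no UMI of Cd3d, Cd3e or Cd3g, against 106 of 434 (24.4%) in the aged and 74 of 348 (21.3%) in the young spleen. In the young brain outside shared barcodes it was 5 of 13 (38.5%, 13.9 to 68.4), so the trait was not seen in the aged brain alone. Unthinned, it was 35 of 83 (42.2%), 1 of 434 (0.230%) and 8 of 350 (2.29%), at a greater depth in spleen. Microglia-like cells of the aged brain, which should lack these genes, had such a UMI in 7 of 4972 (0.141%). Among the 40 cells, 15 had a UMI of Gzmb, against 4 of the 42 cells with CD3, but in the young brain it was 0 of 5 against 1 of 8. Unthinned, 34 of the 35 cells without CD3 had a UMI of Klrb1c, Klrk1 or Klre1 and 16 one of Ncr1, against 37 and 8 of the 48 with CD3. In the young brain these were 5 and 3 of 5, against 8 and 2 of 8. Itga1, the integrin CD49a of tissue-resident lymphocytes, was found in 21 of 82 (25.6%) cells of the aged brain and 36 of 434 (8.29%) of the aged spleen, with 30 of 4972 (0.603%) in microglia-like cells.

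Cluster 1 of the microglia-like cells was led by interferon response genes, with Cxcl10 at 48.1-fold and Ifit3 at 37.8-fold the level of other cells, besides Ccl12 and Lpl. It held 137 cells of the aged brain (1.52%) and 38 of the young brain (0.472%, or 1.13% without shared barcodes). Cluster 25, led by Tbc1d4, Il1r2, Ptgs2 and Atf3, held 220 cells of the aged spleen (4.16%) and 37 of the young spleen (0.583%), and its 334 young brain cells all lay at shared barcodes.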
